A study of Homo sapiens with 30 samples.

How the data were processed

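RNA of 30 libraries was analysed: 10 groups of 3, given by cell line, time and treatment in the labels. Per the labels' protocols, RNA was extracted with RNeasy columns, poly(A) libraries were prepared, and read pairs were sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, the authors used FastQC, Trim Galore, STAR and DESeq2 with GRCh38; versions, the counting tool, its strand setting and the annotation are not given in the sources used here. The deposited values are whole-number counts of reads per Ensembl gene, not normalized, in 1 table of 33538 genes and 30 columns, and each column name matched the title of 1 sample. Of the gene IDs, 33113 were paired with a symbol, 425 were not, and 33456 were found in GENCODE 29, whose GRCh38 coordinates are given; 7105 genes had 0 counts in every library. All labels give batch 1, so no batch could be compared. No pair of libraries differed by as little as counting noise (lowest chi-square per gene 2.195), and each library was counted as 1 replicate.

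Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (16713 kept), library sizes were summed over the genes kept and scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 30 libraries with robust dispersion, so that the groups share one estimate of the spread. Each contrast was tested with glmQLFTest, p was adjusted by Benjamini-Hochberg, and a gene was called at adjusted p under 0.05. Contrasts were BMS-986158 against vehicle in CHLA10, A673 and TC32 at 3 days and in CHLA10 and A673 at 20 days, 6 differences between such effects (20 against 3 days in CHLA10 and A673, and the pairs of lines at each time), and 20-day against 3-day vehicle in CHLA10 and A673. Standard errors are the absolute log2 change divided by the square root of F. CPM and log2 CPM (prior count 2) used the TMM-scaled library sizes. Where a group had 0 counts a fitted change is no bound; list medians are then also given with that gene at its bound against a floor of 3 counts over the group, and intervals and floors cover counting error only.

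The 36 gene lists, the design, the named-gene rule and the other settings were written before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 35 lists with at least 5 genes tested. They covered BET inhibition, EWS::FLI1 targets, adhesion and matrix, cell cycle and survival, signalling, metabolism and stress, and markers of other cell types, and each is named with its result. Counts adjusted over the list alone used only its p-values.

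The text names a fixed set of 16 genes, including PTK2, MYC and IGF1; results of some genes that this set or the rules that follow pick are not reported here. It also names the 5 highest and 5 lowest called genes of each treatment comparison (mean log2 CPM of at least 2, groups not overlapping, which chance gives for 10% of genes, and no clone, antisense or pseudogene-type symbol; the last, ending in P and digits, also left out IGFBP and MMP genes), the 8 highest and 8 lowest shared by the 3 lines, the 4 highest and 4 lowest of each difference, and up to 4 members per list with the largest mean change among those called. Genes with near-identical copies (KRT17, MBD3L3, histone, ribosomal and mitochondrially encoded genes) are uncertain, as are overlapping and antisense genes, since strand is unknown.

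Replicate numbers come from the sample titles. They were checked as pairs by correlating deviations from group means: only CHLA10 at 20 days had each pair over 0.1 (0.20, 0.15 and 0.36), and the blocked value is given there where it changed a call. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size only, no filter, CPM above 1 in 3 libraries, the lines of the contrast only, a replicate block, each replicate left out, the 50 most abundant genes left out, adjusted p under 0.01 and an absolute log2 change of at least 1. The 4 most distant libraries were left out in a fit added after seeing the data. The fit was tested on simulated counts with 200 changed genes. Figures used matplotlib 3.10.9 in Python 3.11.15.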

Results

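Poly(A)-selected RNA was sequenced from 3 Ewing sarcoma cell lines, A673, CHLA10 and TC32, whose genotype label is EWS::FLI1, the fusion transcription factor of this bone and soft tissue tumour. Cells received 5 nM BMS-986158, an inhibitor of the BET bromodomain proteins that read acetylated chromatin, or the solvent DMSO. Treatment lasted 72 hours (labelled 3 days) in all 3 lines and 20 days without a break in CHLA10 and A673. Each of the 10 groups held 3 libraries, 30 in all. The series title concerns dependency on focal adhesion kinase, the product of PTK2, under BET inhibition. The labels do not state how long the 20-day vehicle groups received vehicle. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. CHLA10 was grown in another medium than A673 and TC32, so line and medium cannot be separated.

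Total counts per library ran from 16.1 to 48.9 M (mega). In CHLA10 at 3 days they were 16.5 to 19.7 M for vehicle and 22.2 to 24.9 M for BMS-986158, and at 20 days 17.4 to 20.5 and 25.1 to 26.3 M. In A673 they were 16.5 to 24.7 and 17.4 to 48.9 M at 3 days, and 19.8 to 28.3 and 17.4 to 20.8 M at 20 days. TC32 had 16.1 to 21.3 M under vehicle and 19.5 to 21.8 M under treatment. Of 33538 genes in the table, 16713 passed the filter on low counts and were tested. The libraries farthest from the other members of their group were A673 20-day treated replicate 3 (SD of log2 differences 0.738), A673 3-day vehicle replicate 3 (0.684), CHLA10 20-day treated replicate 3 (0.642) and CHLA10 20-day vehicle replicate 3 (0.573). Below, CPM is given as mean ± SD with n = 3, and log2 changes (BMS-986158 against vehicle) ± the standard error of the edgeR fit.

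The first question was what 3 days of BET inhibition changed in each line. In CHLA10, KRT17, a type I cytokeratin (ENSG00000128422, chromosome 17, 41619441 to 41624842, minus strand, GRCh38), stood at 68.85 ± 3.04 CPM under vehicle and 1.001 ± 0.675 CPM under BMS-986158, a log2 change of -6.11 ± 0.49 (adjusted p = 4.2e-09). Reads of its near-identical pseudogenes make its level uncertain. The smooth muscle actins ACTG2 (-4.84) and ACTA2 (-4.52) fell. So did COL6A3, a collagen VI chain (-4.55 ± 0.44), and NEB, which encodes the muscle protein nebulin (-4.01 ± 0.41). SESN3, which encodes a stress-responsive sestrin, rose from 5.187 ± 0.898 to 80.2 ± 19.7 CPM (log2 change 3.95 ± 0.28, adjusted p = 2.7e-10). TXNIP, a regulator of thioredoxin, rose by 3.36 ± 0.64 and EFR3B by 3.33 ± 0.27. The neural cell adhesion gene NCAM1 rose by 3.22 ± 0.28 and IZUMO4 by 2.87 ± 0.31, with adjusted p of at most 0.000419 for these 4 genes. Of the 16713 genes, 2345 rose and 2630 fell at adjusted p under 0.05, and 566 and 1297 of them at least 2-fold.

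Gene lists were tested with camera. Medians are log2 changes, and both p of a list are adjusted. Among 8 markers of BET inhibition, 5 rose and 1 fell (as many adjusted over the list alone) in CHLA10 at 3 days (median 0.84, adjusted p = 0.000422, or p = 0.211 with an estimated correlation). HEXIM1, an inhibitor of the elongation factor P-TEFb, rose by 1.06 ± 0.12 (adjusted p = 7.91e-08). Of the histone genes that give polyadenylated transcripts, 8 of 14 rose and 0 fell (as many adjusted over the list alone, median 0.60, adjusted p = 4.9e-06, or p = 0.242 with an estimated correlation). EWS::FLI1-activated targets moved the other way: 15 of 23 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.68, adjusted p = 4.9e-06, or p = 0.211 with an estimated correlation). GLI1, a Hedgehog pathway transcription factor, was at -2.65 and the protease gene PAPPA at -2.28. Cell cycle genes of the G1/S phase fell, 18 of 25 fell and 0 rose (19 and 0 adjusted over the list alone, median -0.40, adjusted p = 4.9e-06, or p = 0.416 with an estimated correlation). For MYC targets, 14 of 28 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.30, adjusted p = 0.00125, or p = 0.63 with an estimated correlation). Of extracellular matrix ligands 8 of 37 fell and 1 rose (as many adjusted over the list alone, median -0.43, or -0.35 with genes at 0 counts at their bound, adjusted p = 0.00891, or p = 0.593 with an estimated correlation). Of matrix remodelling enzymes and inhibitors 10 of 26 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.74, adjusted p = 0.00569, or p = 0.593 with an estimated correlation). Of mesenchymal genes 8 of 25 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.56, or -0.62 with genes at 0 counts at their bound, adjusted p = 0.0169, or p = 0.593 with an estimated correlation). COL1A1 was at -1.03 and MMP9, a gelatinase, at -3.94. Of MHC class I antigen presentation genes, 6 of 15 fell and 1 rose (8 and 2 adjusted over the list alone, median -0.92, adjusted p = 0.0396, or p = 0.476 with an estimated correlation). Without treated replicate 3 that list had an adjusted p of 0.0648. Cytosolic ribosomal protein genes rose by a small amount, 14 of 34 rose and 0 fell (as many adjusted over the list alone, median 0.26, adjusted p = 0.000422, or p = 0.8 with an estimated correlation).

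In A673 at 3 days, LAMB3, which encodes a laminin chain, fell from 49.57 ± 20.4 to 1.499 ± 0.475 CPM (log2 change -5.09 ± 0.31, adjusted p = 1.03e-11). CHAC1, a glutathione-degrading enzyme induced in amino acid stress, stood at 46.52 ± 37.5 CPM under vehicle and 1.186 ± 0.451 CPM under treatment (-5.23 ± 0.7, adjusted p = 5.62e-06). The peptide hormone genes ADM2 (-5.03) and SPX (-4.76) fell. EFR3B rose from 1.832 ± 0.623 to 21.51 ± 0.869 CPM (3.57 ± 0.29, adjusted p = 7.52e-10), SIPA1L2 by 3.20 ± 0.52 and the sulfotransferase gene CHST2 by 3.10 ± 0.39. CD24, a surface glycoprotein, rose by 3.03 ± 0.42 and the histone gene H2BC5 by 2.65 ± 0.3, with adjusted p of at most 4.83e-05. In all, 2561 genes rose and 3076 fell, 373 and 1809 of them at least 2-fold.

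Markers of BET inhibition rose in A673 at 3 days, where 7 of 8 rose and 1 fell (as many adjusted over the list alone, median 1.24, adjusted p = 0.000927, or p = 0.165 with an estimated correlation). BET and P-TEFb genes did too, where 5 of 10 rose and 0 fell (as many adjusted over the list alone, median 0.30, adjusted p = 0.00485, or p = 0.212 with an estimated correlation). Histone genes rose too: 12 of 14 rose and 1 fell (as many adjusted over the list alone, median 1.19, adjusted p = 2.15e-08, or p = 0.105 with an estimated correlation). For EWS::FLI1-activated targets, 11 of 23 fell and 2 rose (12 and 2 adjusted over the list alone, median -0.46, adjusted p = 0.000927, or p = 0.284 with an estimated correlation). Insulin-like growth factor (IGF) axis genes fell, and that call held with an estimated correlation: 8 of 16 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.41, adjusted p = 0.000927, or p = 0.0195 with an estimated correlation). IGF2 was at -5.12. Among ATF4 and unfolded protein response genes (the ATF4 list), 16 of 20 fell and 1 rose (as many adjusted over the list alone, median -1.23, adjusted p = 6.86e-07, or p = 0.46 with an estimated correlation). TRIB3 was at -3.53, DDIT4 at -2.70 and the cystine transporter gene SLC7A11 at -1.54. The vehicle libraries stood apart for this list: the treated mean differed by -1.73, -1.37 and -0.16 (log2) from vehicle replicates 1, 2 and 3. Mitochondrial transcripts took 5.31, 5.53 and 2.0% of counts in these 3 libraries and 2.83 to 4.82% under treatment. Of cholesterol synthesis genes, 11 of 20 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.51, adjusted p = 0.00407, or p = 0.933 with an estimated correlation). Oxidative phosphorylation genes fell by little, 8 of 26 fell and 0 rose (as many adjusted over the list alone, median -0.19, adjusted p = 0.0438, or p = 0.933 with an estimated correlation). Camera's adjusted p rose to 0.118, 0.11, 0.0762 and 0.0757 without treated replicate 2, treated replicate 3, vehicle replicate 1 and vehicle replicate 3. MYC targets were higher, 9 of 28 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.0423, or p = 0.933 with an estimated correlation). Camera's adjusted p was 0.0519, 0.0858 and 0.21 without treated replicate 1, vehicle replicate 1 and vehicle replicate 2. Ribosomal protein genes were higher as well, 5 of 34 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.0148, or p = 0.933 with an estimated correlation). Their adjusted p was 0.138 and 0.193 without treated replicate 1 and vehicle replicate 3.

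In TC32, CXCL14, a chemokine gene, fell from 96.61 ± 7.54 to 0.4626 ± 0.324 CPM at 3 days (log2 change -7.67 ± 0.59, adjusted p = 1.56e-09). CRYAB, a small heat shock protein gene, was at -4.99 and NEUROD6, a neuronal transcription factor gene, at -4.98. COL3A1, which encodes collagen III, was at -4.08 and the protocadherin gene PCDH8 at -3.97. NXN, which encodes nucleoredoxin, rose from 2.538 ± 0.715 to 17.05 ± 1.54 CPM (log2 change 2.74 ± 0.22), the kinase gene TESK2 by 2.73 ± 0.26, IZUMO4 by 2.65 ± 0.3 and FAM222A by 2.39 ± 0.43, with adjusted p of at most 8.62e-05. In this line 3728 genes rose and 3817 fell, 833 and 1848 of them at least 2-fold.

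Cell cycle lists fell in TC32. For G1/S genes, 21 of 25 fell and 0 rose (as many adjusted over the list alone, median -0.78, adjusted p = 4.8e-11, or p = 0.267 with an estimated correlation). The replication gene GINS2 was at -1.37. For G2/M genes, 16 of 25 fell and 1 rose (as many adjusted over the list alone, median -0.42, adjusted p = 0.000296, or p = 0.512 with an estimated correlation). The mitotic kinase gene AURKA was at -1.14. Of MHC class I antigen presentation genes, 13 of 15 fell and 0 rose (as many adjusted over the list alone, median -1.37, adjusted p = 4.39e-06, or p = 0.174 with an estimated correlation). Of EWS::FLI1-activated targets 14 of 23 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.66, adjusted p = 0.000468, or p = 0.286 with an estimated correlation). Of repressed targets 9 of 20 fell and 1 rose (as many adjusted over the list alone, median -1.14, adjusted p = 0.0136, or p = 0.658 with an estimated correlation). Of matrix ligands 14 of 37 fell and 3 rose (as many adjusted over the list alone, median -1.02, adjusted p = 0.00363, or p = 0.512 with an estimated correlation). Of remodelling genes 10 of 26 fell and 1 rose (as many adjusted over the list alone, median -0.94, or -1.10 with genes at 0 counts at their bound, adjusted p = 0.00721, or p = 0.514 with an estimated correlation). Of mesenchymal genes, 13 of 25 fell and 1 rose (as many adjusted over the list alone, median -0.70, or -0.86 with genes at 0 counts at their bound, adjusted p = 0.00568, or p = 0.512 with an estimated correlation). Of MYC targets, 15 of 28 fell and 1 rose (as many adjusted over the list alone, median -0.34, adjusted p = 0.00732, or p = 0.658 with an estimated correlation). Of oxidative phosphorylation genes 15 of 26 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.34, adjusted p = 0.00721, or p = 0.514 with an estimated correlation). Of ATF4 list genes 9 of 20 fell and 0 rose (as many adjusted over the list alone, median -0.50, adjusted p = 0.0331, or p = 0.704 with an estimated correlation). Of p53 targets, 8 of 21 fell and 3 rose (as many adjusted over the list alone, median -0.59, adjusted p = 0.0341, or p = 0.467 with an estimated correlation). Without treated replicate 1 that list's adjusted p was 0.0764. BET and P-TEFb genes rose, 6 of 10 rose and 0 fell (as many adjusted over the list alone, median 0.50, adjusted p = 0.00562, or p = 0.267 with an estimated correlation). Markers of BET inhibition did as well, 5 of 8 rose and 1 fell (as many adjusted over the list alone, median 1.01, adjusted p = 0.019, or p = 0.467 with an estimated correlation). Mitochondrially encoded transcripts took 3.82 to 4.74% of counts under treatment and 2.99 to 3.64% under vehicle.

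A set of genes moved in the same direction in the 3 lines at 3 days: 797 rose and 855 fell in each of them, where independent lists of these sizes would share 80.2 and 111. IGF1, which encodes insulin-like growth factor 1 (ENSG00000017427, chromosome 12, 102395874 to 102481744, minus strand), fell from 41.31 ± 4.43 to 5.392 ± 1.01 CPM in CHLA10, from 27.62 ± 3.93 to 3.552 ± 0.221 CPM in A673 and from 29.79 ± 1.32 to 2.478 ± 0.135 CPM in TC32. HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101, plus strand) rose from 87.11 ± 5.25 to 181 ± 15.4 CPM in CHLA10, from 42.43 ± 4.62 to 87.86 ± 4.3 CPM in A673 and from 76.01 ± 1.92 to 149.7 ± 2.27 CPM in TC32. SERPINI1, a neuroserpin gene used as a marker of BET inhibition, rose by 3.20 ± 0.33, 2.38 ± 0.33 and 1.82 ± 0.3 in CHLA10, A673 and TC32. Histone genes H2BC5 (2.37, 2.65 and 1.53 in that order) and H2AC6 (2.51, 2.00 and 1.35) rose with TMTC2, RCBTB2, the talin gene TLN2, DNAJC6, IZUMO4 and the sodium pump gene ATP1B1. For ATP1B1 (1.59, 2.06 and 1.30) the TC32 call was lost without vehicle replicate 1 (1.19, adjusted p = 0.0576). With limma-voom its CHLA10 and TC32 calls were lost (adjusted p = 0.0632 and 0.113). LAMB3 (-3.95, -5.09 and -3.61), the elastin gene ELN (-2.52, -2.36 and -2.73) and EMILIN1, an elastic fibre gene (-3.16, -2.27 and -3.06), fell. PADI2, SYT12, LOXHD1 and the muscle gene MYOM2 fell in each line as well. Of genes called in 2 lines, 94.3% of 2506 had the same direction in CHLA10 and A673, 95.4% of 3193 in CHLA10 and TC32, and 87.9% of 3096 in A673 and TC32.

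**Figure D1:**
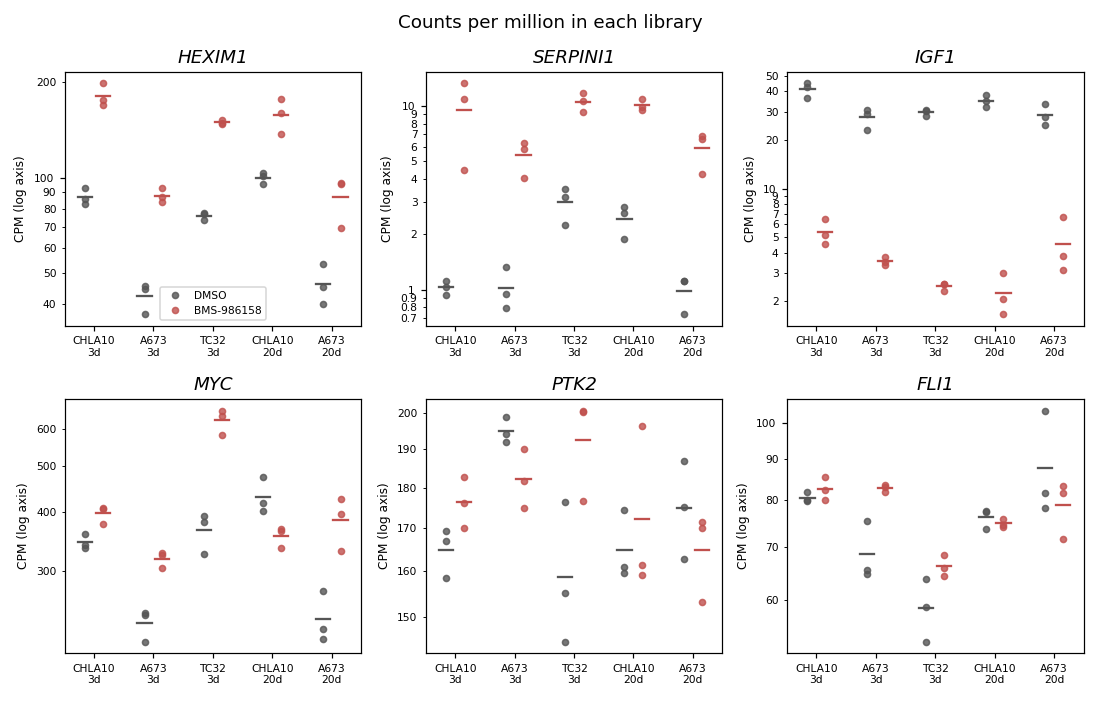
CPM (log axis) of HEXIM1, SERPINI1, IGF1, MYC, PTK2 and FLI1 in each of the 30 libraries, with vehicle in grey, BMS-986158 in red and bars at group means. IGF1 under treatment lies below vehicle in each of the 5 pairs of groups, and HEXIM1 and SERPINI1 lie above.

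**Figure D2:**
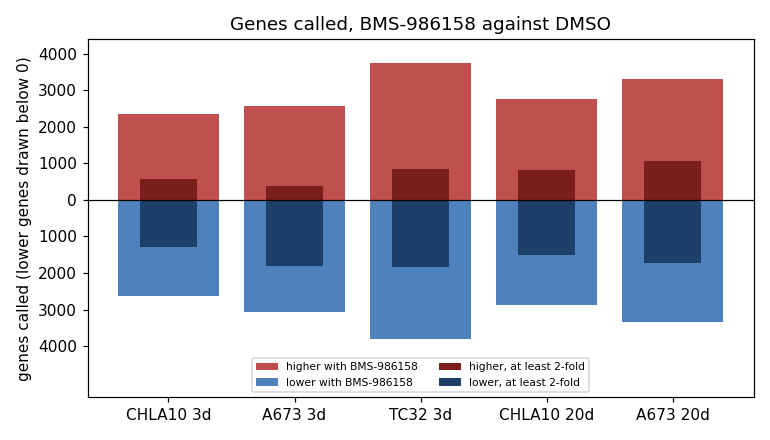
Genes that rose (above 0) and fell (below 0) at edgeR adjusted p under 0.05 in each comparison, with the darker part of each bar for changes of at least 2-fold. In A673 at 3 days 1809 genes fell and 373 rose at least 2-fold.

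The second question was what cells kept in BMS-986158 for 20 days, called persister cells in the labels, expressed. In CHLA10, neuronal genes stood out at 20 days: 13 of 24 rose and 1 fell (as many adjusted over the list alone, median 1.20, adjusted p = 0.000115, or p = 0.081 with an estimated correlation). The microtubule gene MAP2 was at 4.27 ± 0.31 and NCAM1 at 3.31 ± 0.27. ATCAY, a neuronal gene encoding caytaxin, rose from 0.7787 ± 0.512 to 37.22 ± 32 CPM (5.60 ± 0.56, adjusted p = 3.39e-08) and the kinesin gene KIF5C by 5.30 ± 0.5. OSBPL6, a sterol-binding protein gene, and EFR3B rose by 4.45 ± 0.23 and 4.22 ± 0.28. KRT17 fell from 41.77 ± 15.9 to 0.6283 ± 0.238 CPM. ACTG2 (-5.77), LOXHD1 (-5.36), the transcription factor gene TFAP2B (-5.93 ± 0.72) and the neuronal gene NSG2 (-6.04 ± 0.63) fell too. In all, 2754 genes rose and 2873 fell, 804 and 1511 at least 2-fold. Of 2875 genes called at both times, 96.8% had the same direction.

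EWS::FLI1-activated targets fell in CHLA10 at 20 days, 16 of 23 fell and 0 rose (as many adjusted over the list alone, median -0.73, adjusted p = 1.44e-07, or p = 0.081 with an estimated correlation). Extracellular matrix ligands were lower, 12 of 37 fell and 4 rose (as many adjusted over the list alone, median -0.49, or -0.35 with genes at 0 counts at their bound, adjusted p = 0.0315, or p = 0.82 with an estimated correlation). Their adjusted p was 0.0517, 0.0527 and 0.149 without treated replicate 1, treated replicate 2 and vehicle replicate 3, and 0.0817 in the fit paired by replicate block. G1/S genes were higher, 14 of 25 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.32, adjusted p = 0.00186, or p = 0.752 with an estimated correlation). Histone genes were higher too, 5 of 14 rose and 1 fell (as many adjusted over the list alone, median 0.29, adjusted p = 0.0315, or p = 0.752 with an estimated correlation). Of markers of BET inhibition 4 of 8 rose and 1 fell (as many adjusted over the list alone), and camera did not call the list (median 0.53, adjusted p = 0.125). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 6.993 ± 3.55 to 63.6 ± 39 CPM (3.20 ± 0.47, adjusted p = 1.96e-05).

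Whether the response itself changed between 3 and 20 days was tested as a difference of the 2 effects. In CHLA10 it passed for 1057 genes, 560 upward and 497 downward. G1/S genes led, and their call held with an estimated correlation: 20 of 25 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.68, adjusted p = 1.73e-26, or p = 0.0331 with an estimated correlation). For these genes the treated libraries shifted by 0.07 between 3 and 20 days and the vehicle libraries by -0.62. MYC targets moved likewise, 8 of 28 differed upward and 0 downward (16 and 0 adjusted over the list alone, median 0.46, adjusted p = 2.54e-10, or p = 0.578 with an estimated correlation). Ribosomal protein genes moved downward, 9 of 34 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.36, adjusted p = 1.78e-08, or p = 0.889 with an estimated correlation). The treated libraries shifted by -0.03 and -0.06 for these lists and the vehicle libraries by -0.50 and 0.28. Among single genes, the differences were 2.20 ± 0.38 for NCR3LG1, an immune ligand gene, 2.11 ± 0.37 for the ganglioside synthase gene B4GALNT1, 2.06 ± 0.32 for OSBPL6, -3.25 ± 0.41 for H2AC6 and -3.14 ± 0.68 for the cyclin gene CCND2 (adjusted p = 0.0899 with limma-voom). The count fell to 408 and 565 without 3-day treated replicates 1 and 2, and to 581, 456 and 496 without 3-day vehicle replicates 1, 2 and 3. It fell to 690 without 20-day treated replicate 3 and to 357 and 289 without 20-day vehicle replicates 1 and 2, and rose to 1978 without 20-day vehicle replicate 3. It was 1610 in the fit with the replicate block and 1693 with DESeq2.

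In A673 at 20 days, THBS1, which encodes the matrix glycoprotein thrombospondin-1 (ENSG00000137801, chromosome 15, 39581079 to 39599466, plus strand), rose from 2.047 ± 2.23 to 104.2 ± 83.5 CPM (5.62 ± 0.83, adjusted p = 1.43e-05). NT5E, the ecto-nucleotidase CD73, rose from 8.96 ± 3.85 to 326.1 ± 214 CPM (5.18 ± 0.59, adjusted p = 5.12e-07), and LOX, the collagen crosslinking enzyme lysyl oxidase, from 10.02 ± 7.86 to 257.7 ± 200 CPM (4.67 ± 0.6, adjusted p = 2.62e-06). The neural adhesion gene L1CAM rose by 4.61 ± 0.58. SLC38A5, an amino acid transporter gene, fell from 79.81 ± 15.6 to 0.5825 ± 0.358 CPM (-7.05 ± 0.31, adjusted p = 1.27e-15), as did LOXHD1 (-6.05 ± 0.5), the ETS family gene FEV (-6.01 ± 0.32), the sialidase gene NEU4 (-5.49 ± 0.21) and STC2, a secreted hormone gene (-5.15 ± 0.36). In all, 3298 genes rose and 3329 fell, 1060 and 1716 at least 2-fold. With library sizes alone for scaling, which moved the median of all genes to -0.11, 2510 rose and 4251 fell. Of 3671 genes called at both times, 97.2% had the same direction.

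EWS::FLI1-repressed targets rose in A673 at 20 days, 16 of 20 rose and 1 fell (as many adjusted over the list alone, median 2.66, adjusted p = 1.26e-06, or p = 0.38 with an estimated correlation). CD44 was at 4.56. Integrin subunits rose, 11 of 16 rose and 0 fell (as many adjusted over the list alone, median 1.61, adjusted p = 9.89e-06, or p = 0.256 with an estimated correlation). ITGB3 was at 3.10. Extracellular matrix ligands rose, 20 of 37 rose and 5 fell (21 and 5 adjusted over the list alone, median 1.12, or 1.15 with genes at 0 counts at their bound, adjusted p = 5.72e-05, or p = 0.408 with an estimated correlation). YAP/TAZ-TEAD targets rose, 11 of 22 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.64, adjusted p = 0.00859, or p = 0.615 with an estimated correlation). CCN2 was at 3.95. Of mesenchymal genes, 11 of 25 rose and 3 fell (11 and 4 adjusted over the list alone, median 0.84, adjusted p = 0.0192, or p = 0.615 with an estimated correlation). Camera's adjusted p was 0.0533 without treated replicate 2. Over the 109 genes of these 5 lists the median log2 difference from the vehicle mean was 1.19 and 1.17 in treated replicates 1 and 2 and 0.47 in replicate 3, which stood apart. Lysosome and autophagy genes rose, 14 of 23 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.77, adjusted p = 1.16e-06, or p = 0.38 with an estimated correlation). Histone genes were higher, 11 of 14 rose and 0 fell (as many adjusted over the list alone, median 0.87, adjusted p = 3.33e-06, or p = 0.256 with an estimated correlation). So were markers of BET inhibition, 6 of 8 rose and 1 fell (as many adjusted over the list alone, median 1.01, adjusted p = 0.00513, or p = 0.356 with an estimated correlation). EWS::FLI1-activated targets fell, 15 of 23 fell and 2 rose (16 and 2 adjusted over the list alone, median -0.71, adjusted p = 5.48e-07, or p = 0.141 with an estimated correlation). G1/S genes fell, 16 of 25 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.35, adjusted p = 0.00074, or p = 0.615 with an estimated correlation). G2/M genes did too, 11 of 25 fell and 0 rose (as many adjusted over the list alone, median -0.26, adjusted p = 0.015, or p = 0.643 with an estimated correlation). Their adjusted p was 0.119 and 0.0608 without treated replicate 3 and vehicle replicate 1. Oxidative phosphorylation genes were lower, 15 of 26 fell and 1 rose (as many adjusted over the list alone, median -0.33, adjusted p = 0.00859, or p = 0.615 with an estimated correlation), with adjusted p = 0.0746 without treated replicate 3. MYC targets were also lower, 13 of 28 fell and 0 rose (as many adjusted over the list alone, median -0.20, adjusted p = 0.0307, or p = 0.643 with an estimated correlation). Their adjusted p was 0.124 and 0.336 without treated replicate 3 and vehicle replicate 1.

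The A673 response differed between 3 and 20 days for 1214 genes, 724 upward and 490 downward. Upward were the matrix gene TNXB (5.15 ± 0.71), NT5E (5.11 ± 0.79), PDLIM1, an actin-associated gene (4.88 ± 0.78), and LOX (4.86 ± 0.88, adjusted p = 0.12 with limma-voom). Downward were SLC38A5 (-4.02 ± 0.38), the neuropeptide precursor gene VGF (-3.69 ± 0.66) and ESRRB (-3.33 ± 0.57). NOS1 was at -5.53 ± 1.3 and at -9.38 without 20-day treated replicate 3. Extracellular matrix ligands moved upward, 12 of 37 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.07, or 1.08 with genes at 0 counts at their bound, adjusted p = 1.07e-12, or p = 0.14 with an estimated correlation). EWS::FLI1-repressed targets did too, 10 of 20 rose and 0 fell (16 and 0 adjusted over the list alone, median 2.02, adjusted p = 8.2e-13, or p = 0.149 with an estimated correlation), and so did integrin subunits, 8 of 16 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.06, adjusted p = 1.85e-07, or p = 0.14 with an estimated correlation). The treated libraries shifted by 0.83, 2.00 and 0.88 for these lists and the vehicle libraries by 0.02, 0.14 and -0.25. ATF4 list genes moved upward, 8 of 20 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.10, adjusted p = 1.85e-07, or p = 0.211 with an estimated correlation). MYC targets moved downward, 10 of 28 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.44, adjusted p = 1.55e-09, or p = 0.2 with an estimated correlation). Here the treated libraries shifted by 0.24 and -0.03 and the vehicle libraries by -0.69 and 0.41. The count was 778 without 3-day treated replicate 3, 797 and 1937 without 3-day vehicle replicates 2 and 3, 685, 740 and 2346 without 20-day treated replicates 1, 2 and 3 and 775 without 20-day vehicle replicate 1. It was 591 in the fit of A673 libraries alone, and library sizes alone gave 626 upward and 688 downward.

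Responses differed between lines. At 3 days the A673 effect differed from the CHLA10 effect for 1756 genes, the TC32 effect from the CHLA10 effect for 2307 and the TC32 effect from the A673 effect for 4045. For G1/S genes the A673 effect lay above that of CHLA10, 10 of 25 were higher and 0 were lower (13 and 0 adjusted over the list alone, median 0.40, adjusted p = 2.63e-06, or p = 0.833 with an estimated correlation). The TC32 effect lay below that of A673 (median -0.81, adjusted p = 2.27e-12, or p = 0.208 with an estimated correlation), where the list was not called (adjusted p = 0.914). For ATF4 list genes the A673 effect lay below that of CHLA10, 11 of 20 were lower and 0 were higher (12 and 1 adjusted over the list alone, median -0.99, adjusted p = 2.02e-05, or p = 0.833 with an estimated correlation). In CHLA10 the list was at -0.15 and not called (adjusted p = 0.218), and in A673 at -0.16 against vehicle replicate 3 alone. CHAC1 differed by -5.07 ± 0.89, with adjusted p = 0.147 in limma-voom. Counts for A673 against CHLA10 at 3 days were 1101 and 1110 without CHLA10 treated replicates 1 and 2, 1132 without CHLA10 vehicle replicate 3 and 1158 without A673 treated replicate 3. They were 1166 and 2728 without A673 vehicle replicates 2 and 3. Those for TC32 against CHLA10 were 1292 and 1316 without TC32 treated replicates 2 and 3 and 1381 without TC32 vehicle replicate 1.

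At 20 days the A673 and CHLA10 effects differed for 3666 genes, 1904 higher in A673 and 1762 lower. With library sizes alone these were 1538 and 2237. LOX fell in CHLA10, from 261.4 ± 8.47 to 68.49 ± 15.2 CPM, and differed by 6.60 ± 0.79 (adjusted p = 4.64e-06) between the lines. TIAM1, an exchange factor for RAC1, rose from 0.4521 ± 0.215 to 16.99 ± 1.49 CPM in CHLA10 and stood at 16.9 ± 0.553 and 15.57 ± 2.31 CPM in A673 (difference -5.30 ± 0.36, adjusted p = 1.15e-10). For extracellular matrix ligands the A673 effect lay above that of CHLA10, 18 of 37 were higher and 2 were lower (19 and 3 adjusted over the list alone, median 1.33, or 1.34 with genes at 0 counts at their bound, adjusted p = 1.72e-11, or p = 0.178 with an estimated correlation). For neuronal genes the A673 effect lay below that of CHLA10, 10 of 24 were lower and 1 was higher (10 and 2 adjusted over the list alone, median -1.06, or -0.68 with genes at 0 counts at their bound, adjusted p = 0.00156, or p = 0.178 with an estimated correlation). For G1/S genes the A673 effect also lay below, 19 of 25 were lower and 0 were higher (22 and 0 adjusted over the list alone, median -0.64, adjusted p = 1.72e-11, or p = 0.178 with an estimated correlation).

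**Figure D3:**
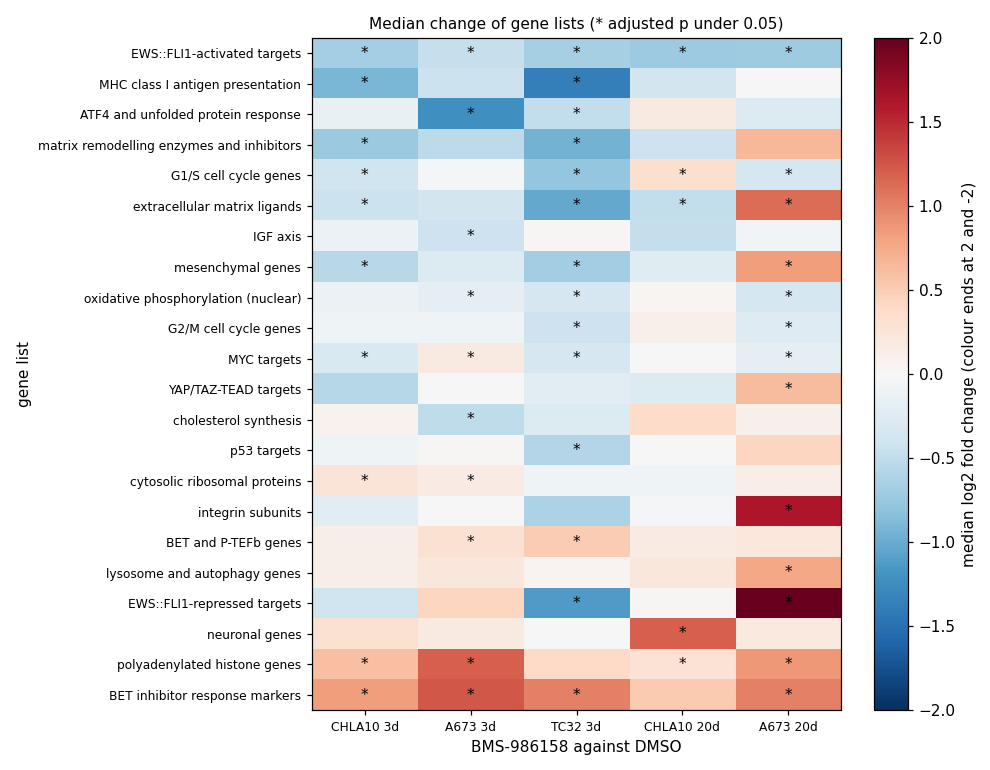
Median log2 change (BMS-986158 against vehicle; colour, with ends at 2 and -2) of 22 gene lists in the 5 treatment comparisons, with an asterisk where camera's adjusted p was under 0.05. EWS::FLI1-repressed targets read 2.66 in A673 at 20 days and -1.14 in TC32 at 3 days.

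Because the title names its product, PTK2 (ENSG00000169398, chromosome 8, 140657900 to 141002216, minus strand) and other adhesion genes were read in each comparison. PTK2 was at 0.10 ± 0.088 (adjusted p = 0.444) in CHLA10, -0.10 ± 0.088 (adjusted p = 0.413) in A673 and 0.28 ± 0.088 (adjusted p = 0.0111) in TC32 at 3 days, and at 0.06 ± 0.088 (adjusted p = 0.632) in CHLA10 and -0.09 ± 0.088 (adjusted p = 0.47) in A673 at 20 days. The TC32 rise, from 158.7 ± 16.1 to 192.6 ± 13.7 CPM, had adjusted p = 0.079 (log2 change 0.22) without vehicle replicate 1. Of 47 focal adhesion components, 6 rose and 15 fell in CHLA10 (7 and 16 adjusted over the list alone), 11 and 12 in A673 (11 and 13) and 15 and 12 in TC32 (16 and 12) at 3 days. At 20 days, 9 rose and 15 fell (as many adjusted over the list alone) in CHLA10 and 19 rose and 8 fell (as many adjusted over the list alone) in A673. Camera called none of the 5 (adjusted p = 0.173, 0.914, 0.545, 0.561 and 0.106); the last was 0.00136 without A673 20-day treated replicate 3. In A673 and TC32 at 3 days the list's median and mean differed in sign. The tensin gene TNS3 fell at 3 days in CHLA10, A673 and TC32 (-2.85, -3.48 and -3.92) and at 20 days in CHLA10 and A673 (-2.13 and -2.30), the last at -1.60 (adjusted p = 0.0604) without vehicle replicate 3. LIMS2, an adhesion adaptor gene, fell in these lines at 3 days (-2.66, -2.90 and -2.58), with adjusted p = 0.103 in A673 with limma-voom. Integrin subunits were called in none of the other 4 comparisons (adjusted p = 0.565, 0.422, 0.425 and 0.659).

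Regulators tied to BET proteins and EWS::FLI1 were also followed. BRD2 rose in each comparison, by 0.52, 0.72 and 0.54 at 3 days in CHLA10, A673 and TC32 and by 0.39 and 0.62 at 20 days in CHLA10 and A673. BRD3 rose in A673 (0.39, adjusted p = 0.000946, and 0.43, adjusted p = 0.000186) and TC32 (0.56, adjusted p = 7.57e-06), with 0.12 (adjusted p = 0.325) and 0.08 (adjusted p = 0.507) in CHLA10. MYC rose in A673 (0.45 ± 0.1, adjusted p = 0.00091 at 3 days and 0.69 ± 0.1, adjusted p = 3.1e-06 at 20 days) and TC32 (0.77 ± 0.1, adjusted p = 6.56e-07), was at 0.20 ± 0.099 (adjusted p = 0.13) in CHLA10 at 3 days and fell there at 20 days (-0.28 ± 0.099, adjusted p = 0.0328). That fall was lost without treated replicates 2 (-0.29, adjusted p = 0.0567) and 3 (-0.23, adjusted p = 0.127) and vehicle replicates 1 (-0.20, adjusted p = 0.187) and 2 (-0.30, adjusted p = 0.0541), and with no filter (adjusted p = 0.0734). MYCN fell in CHLA10 (-1.75, adjusted p = 0.00197, and -2.27, adjusted p = 0.000162), TC32 (-1.43, adjusted p = 0.0152) and A673 at 20 days (-2.08, adjusted p = 0.000171). It was at -0.24 (adjusted p = 0.665) in A673 at 3 days, at -2.70 in CHLA10 without 3-day treated replicate 3, and at -1.04 (adjusted p = 0.103) and -1.06 (adjusted p = 0.105) in TC32 without treated replicate 2 and vehicle replicate 3. EWSR1 passed in no comparison, with log2 changes from -0.19 to 0.16. FLI1 rose in A673 at 3 days (0.27 ± 0.091, adjusted p = 0.0214), a call lost without treated replicate 3 (0.27, adjusted p = 0.0541), vehicle replicate 1 (0.24, adjusted p = 0.0809) and vehicle replicate 2 (0.23, adjusted p = 0.0952), and with RLE factors, no filter and A673 libraries alone (adjusted p = 0.0582, 0.0603 and 0.102). The fusion transcript cannot be told apart from EWSR1 and FLI1 in a table of gene counts. NKX2-2, a fusion target, fell in CHLA10 (-2.07, adjusted p = 0.00703, and -2.09, adjusted p = 0.00156, and -3.45 at 3 days without treated replicate 3) and in A673 at 20 days (-1.59, adjusted p = 3.27e-05). NR0B1, another, was lower in A673 at 20 days (-1.07, adjusted p = 0.00974), with -0.88 (adjusted p = 0.0616), -0.81 (adjusted p = 0.0677) and -1.66 without treated replicates 1, 2 and 3. The cyclin D1 gene CCND1 fell in CHLA10 (-0.61 and -0.73) and A673 (-0.48 and -0.71), with -0.13 (adjusted p = 0.46) in TC32. CDKN1A rose in CHLA10 at 3 days (1.71, adjusted p = 0.00675, or 0.0781 with limma-voom) and in A673 at 20 days (1.38, adjusted p = 0.0108, and 1.09, adjusted p = 0.0668, and 1.16, adjusted p = 0.0564, without treated replicates 1 and 2). IGF1R rose in TC32 (1.17, adjusted p = 0.000304).

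Other lists gave no call by camera in the 5 treatment comparisons; gene values follow the order CHLA10, A673 and TC32 at 3 days, then CHLA10 and A673 at 20 days. Receptor tyrosine kinases had adjusted p of 0.351 to 0.901; the kinase receptor gene ALK (-2.92, -2.10, -2.03, -3.56 and -3.09) fell in each. TGF-beta pathway genes had 0.135 to 0.594, with the ligand gene TGFB3 down in each (-2.10, -1.51, -2.24, -2.50 and -1.49). For BCL2 family genes adjusted p was 0.0985 to 0.538, while BCL2L11, the pro-apoptotic BIM gene, rose in each (1.35, 1.35, 0.97, 1.90 and 1.82). Interferon-stimulated genes had 0.0512 to 0.694. Immediate early genes had 0.0959 to 0.594. Adjusted p for Wnt/beta-catenin targets and regulators was 0.374 to 0.978, for Notch targets 0.485 to 0.899, and for ABC drug transporters 0.471 to 0.74. Mitochondrially encoded transcripts had 0.21 to 0.899. Markers of cell types that a culture could hold passed in no comparison. Epithelial markers had adjusted p of 0.0512 to 0.782, endothelial markers 0.365 to 0.968, and skeletal muscle markers 0.0505 to 0.594. Only 4 blood cell markers were measured, too few to test, with 0 rising and 1, 1, 1, 2 and 2 falling. Leaving out 1 library brought some of these lists under 0.05: epithelial markers in CHLA10 at 3 days (0.0452 and 0.0381 without treated replicate 1 and vehicle replicate 2), interferon-stimulated genes there (0.000106 and 0.0354 without treated replicate 3 and vehicle replicate 3), skeletal muscle markers there (0.0405 without vehicle replicate 1), TGF-beta pathway genes in CHLA10 at 20 days (0.00714 without treated replicate 3) and immediate early genes in A673 at 20 days (0.0308 without treated replicate 3). Of camera's calls in these comparisons, 1 held with an estimated correlation, the IGF axis in A673.

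Vehicle groups labelled for 20 days were compared with those labelled for 3 days, as background for the difference between times. In CHLA10 vehicle cells G1/S genes were lower at 20 days, 24 of 25 fell and 0 rose (as many adjusted over the list alone), a call that held with an estimated correlation (median -0.62, adjusted p = 1.64e-32, or p = 0.0118 with an estimated correlation). MYC targets were lower too, 22 of 28 fell and 0 rose (24 and 0 adjusted over the list alone, median -0.49, adjusted p = 4.88e-16, or p = 0.24 with an estimated correlation). G2/M genes were as well, 13 of 25 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.39, adjusted p = 4.76e-11, or p = 0.361 with an estimated correlation). Extracellular matrix ligands were higher, 10 of 37 rose and 0 fell (as many adjusted over the list alone, median 0.51, or 0.52 with genes at 0 counts at their bound, adjusted p = 0.00163, or p = 0.638 with an estimated correlation). The test called 1346 genes higher and 1180 lower. The count was 1608, 1409 and 1435 without 3-day vehicle replicates 1, 2 and 3 and 1214 and 1292 without 20-day vehicle replicates 1 and 2. In A673 vehicle cells, ATF4 list genes were lower at 20 days, 13 of 20 fell and 0 rose (as many adjusted over the list alone, median -0.80, adjusted p = 6.05e-10, or p = 0.347 with an estimated correlation). MYC targets were higher, 17 of 28 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.40, adjusted p = 2.39e-18, or p = 0.314 with an estimated correlation). There 505 genes were higher and 514 lower, or 327 and 526 with library sizes alone. This count rested on single libraries. It was 12, 16 and 3759 without 3-day vehicle replicates 1, 2 and 3, and 14 and 679 without 20-day vehicle replicates 1 and 3.

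**Figure D4:**
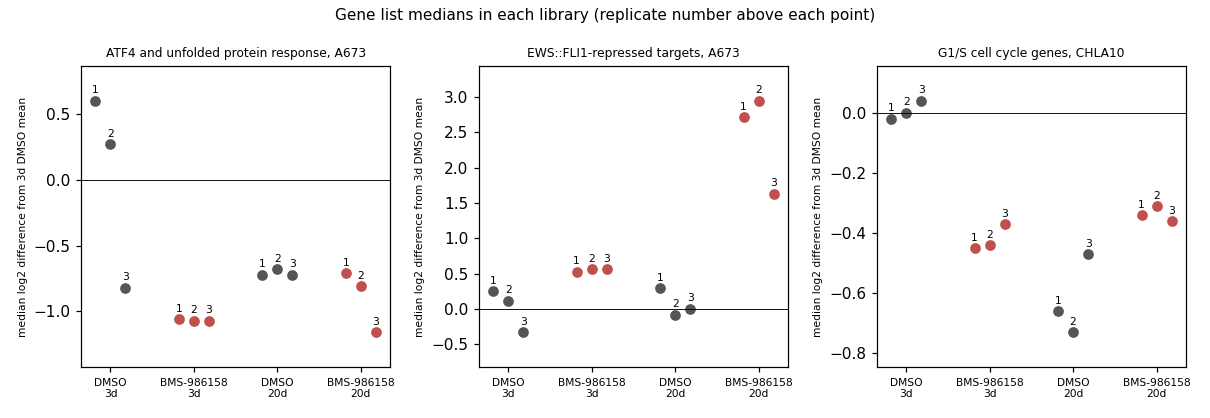
Median log2 difference of each library from the 3-day vehicle mean of its line, for the ATF4 and EWS::FLI1-repressed lists in A673 and the G1/S list in CHLA10; each point is 1 library, vehicle or BMS-986158, at 3 or 20 days. The 3-day vehicle replicates of A673 lie apart for the ATF4 list.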

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

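Of the tests in this part, those of reads from another line, of a single treated library, of vehicle libraries that stand high and of a shift of vehicle libraries were chosen only after the result was seen. First come differences between 2 effects of BMS-986158, tested as interactions in the edgeR fit and given as log2 differences. Counts that moved by over 1.5 times without a single library are given above. For lists, the median log2 difference of a list that camera called is followed by its adjusted p with an estimated correlation.

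Between the effects at 20 and at 3 days in CHLA10, the test passed for 1057 genes and 8 lists. Genes named were IFI6 (3.28), NCR3LG1 (2.20), B4GALNT1 (2.11), OSBPL6 (2.06), TFAP2B (-3.48), H2AC6 (-3.25), CCND2 (-3.14), PKHD1 (-2.87), MYC (-0.48) and IGF1 (-1.02). IFI6 (adjusted p = 0.0431) lost its call when any library but 20-day treated replicate 2 and 3-day treated replicate 3 was left out (adjusted p 0.0587 to 0.12), and was at 5.60 without the latter. TFAP2B was at -1.93 (adjusted p = 0.0641) and PKHD1 at -2.02 (adjusted p = 0.0525) without 3-day treated replicate 3, and TFAP2B lost its call without 3-day vehicle replicates 2 and 3, 20-day treated replicate 3 and 20-day vehicle replicates 1 and 2 (adjusted p 0.0531 to 0.0648). MYC lost its call when any library but 3-day treated replicate 3 and 20-day vehicle replicate 3 was left out (adjusted p 0.0509 to 0.137). IGF1 lost its call when any library but 3-day treated replicate 2, 20-day treated replicate 3 and 20-day vehicle replicate 3 was left out (adjusted p 0.0552 to 0.0982). The list values were -0.23 and 0.889 for histone, 0.46 and 0.578 for MYC targets, 0.68 and 0.0331 for G1/S, 0.21 and 0.889 for G2/M, 1.35 (at the bound 1.28) and 0.889 for interferon, 0.34 and 0.902 for ATF4, 0.51 and 0.578 for neuronal, -0.36 and 0.889 for ribosomal.

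Between the effects at 20 and at 3 days in A673, the test passed for 1214 genes and 16 lists. Genes named were TNXB (5.15), NT5E (5.11), PDLIM1 (4.88), LOX (4.86), NOS1 (-5.53), SLC38A5 (-4.02), VGF (-3.69), ESRRB (-3.33), MYCN (-1.84), FLI1 (-0.43) and NKX2-2 (-1.57). NOS1 was at -9.38 without 20-day treated replicate 3. MYCN lost its call when any library but 3-day vehicle replicate 3, 20-day treated replicate 3 and 20-day vehicle replicate 2 was left out (adjusted p 0.05 to 0.0944). FLI1 lost its call when any library but 3-day vehicle replicate 3 and 20-day vehicle replicates 2 and 3 was left out (adjusted p 0.0512 to 0.167). The list values were -0.44 and 0.2 for MYC targets, -0.31 and 0.2 for EWS::FLI1-activated, 2.02 and 0.149 for EWS::FLI1-repressed, 0.29 and 0.498 for focal adhesion, 1.06 and 0.14 for integrin, 1.07 (at the bound 1.08) and 0.14 for matrix ligand, 0.73 and 0.274 for matrix remodelling, 1.03 and 0.2 for YAP/TAZ, 1.00 (at the bound 0.91) and 0.2 for mesenchymal, -0.31 and 0.235 for G1/S, -0.20 and 0.662 for G2/M, 0.39 and 0.2 for TGF-beta, 0.61 and 0.25 for cholesterol, 0.62 and 0.211 for MHC class I, 1.10 and 0.211 for ATF4, 0.44 and 0.211 for lysosome.

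Between the A673 and CHLA10 effects at 3 days, the test passed for 1756 genes and 5 lists. Genes named were TMEM114 (4.43), CRYGS (4.38), KCNE3 (4.36), ACTA2 (4.29), ZIC2 (-5.53), CHAC1 (-5.07), XG (-3.77), PRAME (-3.57) and NKX2-2 (2.06). ZIC2 had 0 counts in the CHLA10 vehicle group, so its value depends on the prior count, and its adjusted p was 0.0915 and 0.0518 without CHLA10 treated replicates 1 and 2 and 0.0664, 0.0768 and 0.0753 without vehicle replicates 1, 2 and 3. NKX2-2 lost its call when any library but CHLA10 treated replicate 3, A673 treated replicate 2 and A673 vehicle replicates 2 and 3 was left out (adjusted p 0.054 to 0.134), and was at 3.44 without CHLA10 treated replicate 3. The list values were 0.49 and 0.833 for MYC targets, 0.31 (at the bound 0.35) and 0.942 for mesenchymal, 0.40 and 0.833 for G1/S, -0.52 and 0.918 for cholesterol, -0.99 and 0.833 for ATF4.

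Between the TC32 and CHLA10 effects at 3 days, the test passed for 2307 genes and 11 lists. Genes named were UNCX (3.97), CRYGS (3.48), NETO1 (3.21), ITPR3 (2.81), KIF5C (-3.55), CADM1 (-3.23), NCAM1 (-3.19), FREM1 (-3.08), MYC (0.57), SERPINI1 (-1.38), BRD3 (0.45), NKX2-2 (2.20) and CDKN1A (-2.58). SERPINI1 lost its call when any library but CHLA10 treated replicate 3, TC32 treated replicate 1 and TC32 vehicle replicate 1 was left out (adjusted p 0.0568 to 0.129). BRD3 lost its call without TC32 treated replicates 2 and 3 (adjusted p = 0.0634 and 0.0518). NKX2-2 lost its call without CHLA10 treated replicates 1 and 2 and CHLA10 vehicle replicate 2 (adjusted p = 0.0819, 0.0681 and 0.0508), and was at 3.59 without CHLA10 treated replicate 3. The list values were -0.57 and 0.698 for histone, -0.48 and 0.823 for EWS::FLI1-repressed, 0.18 and 0.823 for focal adhesion, -0.23 and 0.698 for G1/S, -0.30 and 0.723 for G2/M, -0.61 and 0.398 for p53 targets, -0.62 and 0.262 for BCL2, -0.40 and 0.823 for cholesterol, -0.53 and 0.698 for MHC class I, -0.41 and 0.698 for ribosomal, -0.23 and 0.698 for oxidative phosphorylation.

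Between the TC32 and A673 effects at 3 days, the test passed for 4045 genes and 11 lists. Genes named were FLRT1 (4.95), CHAC1 (4.81), VLDLR (3.85), XG (3.57), KRT17 (-4.15), ADM (-4.12), LMCD1 (-3.70), COL3A1 (-3.55), PTK2 (0.38) and IGF1R (0.97). KRT17 was at -7.85 without TC32 treated replicate 1. PTK2 lost its call when any library but A673 treated replicate 1, A673 vehicle replicates 1 and 3, TC32 treated replicate 1 and TC32 vehicle replicate 2 was left out (adjusted p 0.0519 to 0.106). IGF1R lost its call when any library but A673 vehicle replicates 1 and 2, TC32 treated replicate 1 and TC32 vehicle replicate 3 was left out (adjusted p 0.0535 to 0.13). The list values were -0.50 and 0.726 for histone, -0.59 and 0.726 for MYC targets, -0.88 and 0.757 for EWS::FLI1-repressed, -0.73 (at the bound -0.70) and 0.757 for matrix ligand, -0.64 (at the bound -0.57) and 0.766 for matrix remodelling, -0.81 and 0.208 for G1/S, -0.36 and 0.766 for G2/M, -0.41 and 0.208 for BCL2, -0.73 and 0.208 for MHC class I, 0.59 and 0.766 for ATF4, -0.30 and 0.766 for ribosomal.

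Between the A673 and CHLA10 effects at 20 days, the test passed for 3666 genes and 17 lists. Genes named were LOX (6.60), TGFB2 (6.55), HCLS1 (5.81), LIMS2 (5.68), LGR5 (-6.14), TIAM1 (-5.30), VGF (-5.11), XG (-4.96), MYC (0.97), BRD3 (0.35), NR0B1 (-1.25), CDKN1A (-1.83) and IGF1 (1.31). HCLS1 had 0 counts in the CHLA10 treated group, so its value depends on the prior count. XG was at -9.11 without A673 treated replicate 3. BRD3 lost its call when any library but CHLA10 vehicle replicate 2 and A673 treated replicate 1 was left out (adjusted p 0.0526 to 0.0817). NR0B1 lost its call when any library but CHLA10 treated replicate 3 and A673 treated replicate 3 was left out (adjusted p 0.0695 to 0.127). CDKN1A lost its call when any library but CHLA10 treated replicates 1 and 2, CHLA10 vehicle replicate 3 and A673 treated replicates 1 and 2 was left out (adjusted p 0.055 to 0.146), and was at -1.20 without CHLA10 treated replicate 3. The list values were 0.52 and 0.476 for histone, -0.30 and 0.476 for MYC targets, 2.32 and 0.219 for EWS::FLI1-repressed, 0.27 and 0.62 for focal adhesion, 1.27 and 0.178 for integrin, 1.33 (at the bound 1.34) and 0.178 for matrix ligand, 1.05 and 0.551 for matrix remodelling, 1.42 and 0.435 for YAP/TAZ, 0.94 (at the bound 1.01) and 0.178 for mesenchymal, -0.64 and 0.178 for G1/S, -0.32 and 0.476 for G2/M, 0.56 and 0.321 for TGF-beta, -1.06 (at the bound -0.68) and 0.178 for neuronal, 0.32 and 0.476 for lysosome, 0.24 and 0.756 for ribosomal, -0.31 and 0.476 for oxidative phosphorylation, 0.61 and 0.746 for mitochondrial.

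Other splits of the same libraries were refitted. For the comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split and the highest other called 4975 and 1 genes (CHLA10 at 3 days), 5637 and 76 genes (A673 at 3 days), 7545 and 586 genes (TC32 at 3 days), 5627 and 46 genes (CHLA10 at 20 days), 6627 and 1683 genes (A673 at 20 days), 2526 and 0 genes (CHLA10 vehicle) and 1019 and 1245 genes (A673 vehicle). Splits with as many genes, the real one included, numbered 1 for each but A673 vehicle, with 2, where the higher split exchanged 20-day vehicle replicate 2 with 3-day vehicle replicate 3. In the 9 other splits of CHLA10 vehicle, edgeR called 0 genes, with 252 to 1798 at an unadjusted p under 0.05. Of the CHLA10 20-day splits that part as many of the 3 pairs as the real one, the others called 1, 0 and 0 genes. For genes up and down in each of the 3 lines, 1 of 100 splits gave as many (904 and 1111 in a fit of the 3-day libraries, highest other 73 for both). In 100 splits of the 12 libraries of each difference, as many genes came from 1 (A673 against CHLA10 at 3 days; 2766, highest other 1840), 2 (the CHLA10 times; 1336 and 1841), 2 (TC32 against A673; 4104 and 4353), 3 (TC32 against CHLA10; 4267 and 4661), 3 (A673 against CHLA10 at 20 days; 2473 and 6302) and 6 (the A673 times; 591 and 7341). The shares of 100 decide nothing about chance: exchanging treated and vehicle libraries mixes the groups, which gave a median of 0 genes. For differences it can also mirror an effect, so that the effects add, as with 7341 and 6302 genes.

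The first pattern is the rise of matrix ligand, integrin, YAP/TAZ, mesenchymal and EWS::FLI1-repressed lists in A673 at 20 days, with a median of 0.94 over 109 members, 61 of which rose. Reads of another line are argued against: the median of 15 genes private to CHLA10 was at most 0.0914% of their own level in each A673 20-day treated library, where the risen members would need a median share of 161% of CHLA10 or 235% of TC32. Scaling is argued against, since library size only gave 0.81. A single treated library as the cause is argued against as well: the treated medians were 1.19, 1.17 and 0.47, and those of the vehicle libraries -0.04 to 0.04. The longer exposure that the design names stays open, untested.

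The second pattern is the fall of the ATF4 list in A673 at 3 days. A swap with a 20-day vehicle library is argued against, since each of those lies closer to its own group than to 3-day vehicle replicates 1 and 2, by at least 0.17 (SD of log2 differences). Vehicle replicates 1 and 2 standing high could account for the fall, since against vehicle replicate 3 alone the median difference was -0.16. A wrong label on vehicle replicate 3 alone stays open, as it lies 0.73 from replicates 1 and 2 and 0.51 from the 20-day vehicle libraries. So does an effect of the inhibitor on ATF4 targets, which was not tested apart from these libraries.

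The third pattern is the rise of the G1/S list in CHLA10 between the effects at 3 and 20 days. Scaling is argued against, since library size only gave 0.66. A shift of the vehicle libraries could account for it: the treated libraries moved by 0.07 between the times and the vehicle libraries by -0.62. Culture length, density or medium of the vehicle cells, and a recovery of cycling in treated cells relative to them, stay open and were not tested.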

How the results depend on the processing

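The fits without the 4 most distant libraries, and the gene list tests with 1 replicate left out, were chosen after seeing the data; the other alternatives were planned. Across RLE factors, upper-quartile factors, library size only, limma-voom, no filter, the CPM filter and the 50 most abundant genes left out, counts of genes called stayed within 1.5 times those reported. At adjusted p under 0.01 they were 3194 for CHLA10 at 3 days, 3682 for A673 at 3 days, 3719 for CHLA10 at 20 days, 229 for the CHLA10 times, 474 for the A673 times, 699 for A673 against CHLA10 at 3 days, 919 for TC32 against CHLA10, 2186 for TC32 against A673, 2084 for A673 against CHLA10 at 20 days, 1168 for CHLA10 vehicle, 69 for A673 vehicle, 486 for genes up in the 3 lines and 510 for genes down in the 3 lines. With an absolute log2 change of at least 1 they were 1863 for CHLA10 at 3 days, 2182 for A673 at 3 days, 2681 for TC32 at 3 days, 2315 for CHLA10 at 20 days, 2776 for A673 at 20 days, 360 for the CHLA10 times, 534 for the A673 times, 847 for A673 against CHLA10 at 3 days, 780 for TC32 against CHLA10, 1579 for TC32 against A673, 1781 for A673 against CHLA10 at 20 days, 442 for CHLA10 vehicle, 246 for A673 vehicle, 76 for genes up in the 3 lines and 397 for genes down in the 3 lines; both thresholds are stricter by construction. DESeq2 gave 1693 for the CHLA10 times and 1632 for A673 vehicle, and fits on the lines of the contrast only gave 591 for the A673 times and 0 for A673 vehicle; the cause was not tested. For that 0, edgeR found 3110 genes at an unadjusted p under 0.05, while limma-voom and DESeq2 on all libraries called 1178 and 1632. With 1 replicate left out, counts ran from 289 to 1978 for the CHLA10 times, from 1214 to 2922 for CHLA10 vehicle, from 685 to 2346 for the A673 times, from 1101 to 2728 for A673 against CHLA10 at 3 days, from 12 to 3759 for A673 vehicle and from 1292 to 3146 for TC32 against CHLA10. Without the 4 most distant libraries counts were 3154 for the CHLA10 times, 4331 for the A673 times, 4691 for A673 against CHLA10 at 3 days, 4689 for TC32 against CHLA10, 5527 for A673 against CHLA10 at 20 days, 4975 for CHLA10 vehicle, 5756 for A673 vehicle and 1271 for genes up in the 3 lines. These libraries were picked for their distance, so that fit understates the spread: its common biological coefficient of variation was 9.8%, against 16% with all 30, and it held 89.1 to 100% of the reported genes.

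Replicate numbers paired the samples in CHLA10 at 20 days only, where 5 of 6 libraries correlated best with their own number. Correlations of deviations of same-numbered libraries were 0.03, 0.00 and 0.01 in CHLA10 at 3 days (2 of 6), -0.02, 0.05 and -0.02 in A673 at 3 days (2 of 6), 0.10, 0.07 and 0.03 in TC32 (5 of 6), and 0.16, -0.16 and 0.10 in A673 at 20 days (2 of 6). With the replicate block, 1610 for the CHLA10 times was the count that moved by over 1.5 times. Lists gained with the block were, with adjusted p, in CHLA10 at 3 days, YAP/TAZ (0.0212), interferon (0.0191), neuronal (0.0212) and skeletal muscle (0.038); in TC32 at 3 days, immediate early (0.0471); in A673 at 20 days, focal adhesion (0.0385), TGF-beta (0.0323) and immediate early (0.0352). Those lost were in A673 at 3 days, oxidative phosphorylation (0.0692); in CHLA10 at 20 days, matrix ligand (0.0817). The block changed no other list call.

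Camera with an estimated correlation raised the adjusted p of 51 lists called in the treatment comparisons over 0.05: in CHLA10 at 3 days, BET inhibitor markers (0.211), histone (0.242), MYC targets (0.63), EWS::FLI1-activated (0.211), matrix ligand (0.593), matrix remodelling (0.593), mesenchymal (0.593), G1/S (0.416), MHC class I (0.476) and ribosomal (0.8); in A673 at 3 days, BET and P-TEFb (0.212), BET inhibitor markers (0.165), histone (0.105), MYC targets (0.933), EWS::FLI1-activated (0.284), cholesterol (0.933), ATF4 (0.46), ribosomal (0.933) and oxidative phosphorylation (0.933); in TC32 at 3 days, BET and P-TEFb (0.267), BET inhibitor markers (0.467), MYC targets (0.658), EWS::FLI1-activated (0.286), EWS::FLI1-repressed (0.658), matrix ligand (0.512), matrix remodelling (0.514), mesenchymal (0.512), G1/S (0.267), G2/M (0.512), p53 targets (0.467), MHC class I (0.174), ATF4 (0.704) and oxidative phosphorylation (0.514); in CHLA10 at 20 days, histone (0.752), EWS::FLI1-activated (0.081), matrix ligand (0.82), G1/S (0.752) and neuronal (0.081); in A673 at 20 days, BET inhibitor markers (0.356), histone (0.256), MYC targets (0.643), EWS::FLI1-activated (0.141), EWS::FLI1-repressed (0.38), integrin (0.256), matrix ligand (0.408), YAP/TAZ (0.615), mesenchymal (0.615), G1/S (0.615), G2/M (0.643), lysosome (0.38) and oxidative phosphorylation (0.615). Library size only brought under 0.05 in CHLA10 at 3 days, BET and P-TEFb (0.0435), neuronal (0.0488) and skeletal muscle (0.0488). Without the 4 most distant libraries the lists gained were in CHLA10 at 3 days, BET and P-TEFb (0.0455), focal adhesion (0.0319), YAP/TAZ (0.0192), neuronal (0.025) and epithelial (0.0281); in A673 at 3 days, matrix remodelling (0.00654); in TC32 at 3 days, histone (0.0297) and immediate early (0.0274); in CHLA10 at 20 days, matrix remodelling (0.00724), mesenchymal (0.021), G2/M (0.00724), TGF-beta (0.0437), cholesterol (0.000457) and epithelial (0.0114); in A673 at 20 days, focal adhesion (0.000132), matrix remodelling (0.00215), TGF-beta (0.0218), immediate early (0.000525) and MHC class I (0.0375). Those lost were in A673 at 3 days, ribosomal (0.177) and oxidative phosphorylation (0.177); in A673 at 20 days, MYC targets (0.0927), G2/M (0.0858) and oxidative phosphorylation (0.0767). With 1 replicate left out, lists that crossed 0.05 had these ranges of adjusted p: in CHLA10 at 3 days, BET and P-TEFb (0.0268 to 0.124), interferon (0.000106 to 0.193), MHC class I (0.0251 to 0.0648), skeletal muscle (0.0405 to 0.115), neuronal (0.0345 to 0.0869) and epithelial (0.0381 to 0.106); in A673 at 3 days, MYC targets (0.0031 to 0.21), ribosomal (0.000967 to 0.193) and oxidative phosphorylation (0.00753 to 0.118); in TC32 at 3 days, histone (0.00577 to 0.242), p53 targets (0.0238 to 0.0764) and ribosomal (0.00898 to 0.812); in CHLA10 at 20 days, MYC targets (0.0499 to 0.322), matrix ligand (0.00354 to 0.149), matrix remodelling (0.00264 to 0.645), mesenchymal (0.00714 to 0.438), TGF-beta (0.00714 to 0.589), lysosome (0.0392 to 0.279) and cholesterol (0.000877 to 0.629); in A673 at 20 days, BET and P-TEFb (0.041 to 0.157), MYC targets (0.00533 to 0.336), matrix remodelling (0.0109 to 0.433), immediate early (0.0308 to 0.283), focal adhesion (0.00136 to 0.217), mesenchymal (0.000444 to 0.0533), G2/M (0.00299 to 0.119) and oxidative phosphorylation (0.00256 to 0.0746). The cause was not tested for these lists.

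No call of a named gene turned its direction under the alternatives, nor did a list call in the 5 treatment comparisons under those run for lists, which this part names. Whether more genes went up or down turned with scaling in several differences, as with 518 upward and 534 downward between the CHLA10 times with upper-quartile factors. The difference between the A673 times for IGF1R, 0.02 and not called (adjusted p = 1), was -0.73 and called (adjusted p = 0.00349) without the 4 most distant libraries; the cause was not tested. Of 16712 alternative values for 939 results of named genes, 228 changed sign without being called in either fit. Named genes lost and gained calls as follows: 53 and 12 with limma-voom, 4 and 29 with DESeq2, 9 and 13 with library size only, 33 and 0 without a filter, 33 and 30 with the lines of the contrast only, and 396 and 48 over all fits with 1 replicate left out. Depth sets the limit of 3 counts that a group at 0 allows. On simulated data for CHLA10 at 3 days, 44% of genes changed 1.5-fold and 86% of those changed 2-fold were recovered over 16437 genes, and for the difference between the CHLA10 times 14% and 64% over 16440; what limited recovery was not tested.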

Other observations

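The tests in this part were planned. Beyond the lists described above, vehicle cells differed between the groups labelled 20 and 3 days in further gene groups. In CHLA10, TGF-beta pathway genes (median 0.43, adjusted p = 0.0053, or p = 0.549 with an estimated correlation), MHC class I antigen presentation genes (median 0.53, or 0.50 with genes at 0 counts at their bound, adjusted p = 0.0168, or p = 0.549 with an estimated correlation), EWS::FLI1-repressed targets (median 0.69, adjusted p = 0.0298, or p = 0.85 with an estimated correlation), integrin subunits (median 0.38, adjusted p = 0.0466, or p = 0.68 with an estimated correlation) and ribosomal protein genes (median 0.28, adjusted p = 6.17e-07, or p = 0.68 with an estimated correlation) were higher at 20 days by camera. Cholesterol synthesis genes (median -0.36, adjusted p = 0.00977, or p = 0.85 with an estimated correlation) and ATF4 list genes (median -0.43, adjusted p = 0.0164, or p = 0.85 with an estimated correlation) were lower. In A673 vehicle cells, G1/S (median 0.29, adjusted p = 4.34e-10, or p = 0.347 with an estimated correlation) and G2/M genes (median 0.23, adjusted p = 0.000222, or p = 0.734 with an estimated correlation) were higher at 20 days. There p53 targets (median -0.25, adjusted p = 0.0162, or p = 0.347 with an estimated correlation), immediate early genes (median -0.51, adjusted p = 0.00805, or p = 0.743 with an estimated correlation), cholesterol synthesis genes (median -0.26, adjusted p = 0.00852, or p = 0.996 with an estimated correlation) and mitochondrially encoded transcripts (median -0.90, adjusted p = 4.99e-06, or p = 0.734 with an estimated correlation) were lower. Mitochondrial transcripts took 5.31 and 5.53% of counts in 3-day vehicle replicates 1 and 2, 2.0% in replicate 3 and 1.68 to 2.96% in the 20-day vehicle libraries.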
